A study of Mus musculus with 12 samples.

How the data were processed

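Polyadenylated RNA of Ly6G+ spleen cells from mice aged 2 days, 7 days, 14 days and 6 weeks was sequenced, with 3 libraries per age. Per the labels' protocols, RNA was extracted with Trizol, first-strand cDNA was primed with random hexamers, and adapter-ligated fragments were amplified by PCR. The labels do not say whether strand was kept, so reads of a gene and of an antisense partner cannot be told apart. They give neither sex, strain, batch nor the number of mice per library.

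The submitters deposited 1 table of whole-number counts per gene for the 12 libraries. Per the submitters' processing notes, RSEM 1.2.3, DESeq2 (no version given) and the mouse genome build mm10 were used. The notes do not say what each tool did. RSEM gives estimated counts, which divide reads among similar genes, so the deposited counts may be such estimates rounded to whole numbers. How reads of paralogs, pseudogenes and overlapping genes were divided is then a property of that step and is uncertain for stefin A, heat-shock 70, haemoglobin, Ifit, Oas1, Ear and class I genes. The table held 38887 Ensembl gene identifiers, and 37570 of them were given a symbol and a position from GENCODE M21, whose assembly GRCm38 is that of mm10. The other 1317 stayed in the library totals.

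Totals ran from 34495767 to 38795913 counts per library, so counting error is small for all but the rarest transcripts. A level of 0 counts in the 3 libraries of an age was treated as at most 3 counts over the age, and folds against such an age are lower bounds from that floor. Libraries were grouped by the age in the labels. Counts were normalized with trimmed mean of M-values factors, and 15494 genes passed the expression filter of edgeR (filterByExpr, minimum count 10). The main test was edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) with 1 model over all 12 libraries and age as the only term. This lets each comparison share an estimate of the spread across 4 ages. P-values were adjusted over genes by the Benjamini-Hochberg method, with a threshold of 0.05. The 6 pairs of ages and a joint test of any difference were examined. SE values are the absolute log2 fold change divided by the square root of the F statistic. CPM values use the normalized library sizes.

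Gene lists were fixed before the data were examined, from textbook knowledge of neutrophils and other spleen cells. Those about the cells themselves covered type I interferon-stimulated genes, interferon receptors and proximal signalling, the NF-kB pathway and its inflammatory targets, suppressive mediators of myeloid cells, lactoferrin and its candidate receptors, primary granules, secondary granules, mature neutrophils, NADPH oxidase and granulocyte progenitor regulators. Further lists covered the cell cycle, the unfolded protein response, glycolysis, oxidative phosphorylation, cholesterol synthesis, lipid uptake and fatty acid metabolism, class I antigen presentation, pattern recognition receptors, a fetal-type program, immediate early and handling response genes, and ribosomal proteins. The list of immediate early and handling response genes, called immediate early genes below, also held the heat-shock genes Hspa1a and Hspa1b. Markers of other cell types covered erythroid cells, B cells and MHC class II, T and NK cells, monocytes and macrophages, megakaryocytes and platelets, eosinophils with basophils and mast cells, dendritic cells, and stromal and endothelial cells. The 29 lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists, in 4 comparisons. A further list of sex-linked genes was given as values only. Lists share members, so their tests are not independent.

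Single genes were named by a rule also set beforehand. For each age against 6 weeks it took the 5 largest rises and 5 largest falls among called genes with a mean of 20 CPM or more at the higher age and no overlap between the libraries of the 2 ages. Predicted genes, pseudogenes and immunoglobulin and T cell receptor segments were left out of these. It added a fixed set of genes on interferon, suppression, inflammation and granules whatever their values, and the 2 members with the smallest p from each list called. For pairs of younger ages it took the 3 largest changes each way. Some genes that the rule named are not reported here.

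The procedure was tested on simulated counts with known changes, in the comparison of 2 days with 6 weeks. Gene means for the simulation came from the 6-week libraries alone. The rates below therefore do not describe the expression profile or the spread of the 2-day libraries. Of genes changed by 1 on the log2 scale 56% were called, of those changed by -1 51.06%, by 2 90% and by -2 91.49%. Unchanged genes made up 6.04% of the calls. Of 14705 simulated genes 14511 were unchanged, far fewer changes than were called in the real comparison, so these rates may differ there. A list shifted by 0.5, that of the cell cycle, was called and 0 of the others. The simulated genes varied independently of each other, so this does not show how camera behaves where the genes of a list are correlated. In the real comparison of 2 days with 6 weeks the estimated correlation of the cell cycle list was 0.856.

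Alternatives set before the data were examined were other normalizations (relative log expression, upper quartile, library totals alone), no filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a block for the replicate number, each library left out in turn, erythroid genes left out, fits on only 2 ages, camera with an estimated correlation, and fry. Fits without 2-day replicate 2 and 14-day replicate 1 together, and without all 7-day libraries, were chosen after the data were seen. The closing section gives their effects. No library was left out of the main results.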

Results

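Transcripts of Ly6G+ spleen cells of mice were sequenced at 4 ages: 2 days, 7 days, 14 days and 6 weeks after birth. Ly6G is a surface protein of neutrophils, and the labels call the cells of every age polymorphonuclear myeloid-derived suppressor cells, neutrophils that can restrain T cells. The series asks what controls a suppressive activity that neutrophils of newborn mice hold for a short time. Each age had 3 libraries, 12 in all, with totals of 34495767 to 38795913 counts. All 12 totals thus lay close together, and between 18912 and 20255 genes had at least 1 count in a library. Nothing in the labels says whether the 3 libraries of an age came from separate mice, so the p-values measure the spread between these libraries, which may be technical. At 7 days the Y-linked and Xist levels given below argue against repeats of 1 RNA sample. Expression values are mean CPM (counts scaled to the normalized size of each library) ± SD of 3 libraries, and fold changes are given with the standard error (SE) of their log2 value.

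Libraries of different ages lay apart. The first principal component of log2 CPM carried 42% of the variance and set the 2-day and 7-day libraries against those of 14 days and 6 weeks. The second component, with 26.7%, set 2 days against 7 days. The mean Spearman correlation across genes was lowest between 2 days and 6 weeks, at 0.932, and highest between 14 days and 6 weeks, at 0.971. Within an age, 2-day replicate 2 correlated with its partners at 0.971 and 0.98, against 0.992 for the other pair, and 14-day replicate 1 at 0.986, against 0.994. Their normalization factors were 0.828 and 0.918. Transcripts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 3051 to 3299 counts in each 2-day library and 1816 to 4010 in each 7-day library. At 14 days and 6 weeks, 0 or 1 such count was found per library. The X-linked Xist, which female cells transcribe, was present at every age, with 183 ± 24.2 CPM at 2 days and 256 ± 41.2 CPM at 6 weeks. The 2-day and 7-day libraries therefore held both Xist and Y-linked transcripts, and the older ones Xist with at most 1 Y-linked count. The sex of the mice thus cannot be told apart from age where 2 or 7 days is compared with 14 days or 6 weeks. In 7-day replicates 1, 2 and 3 Xist was at 309, 442 and 187 CPM, Ddx3y at 24.8, 32.8 and 50 CPM and Eif2s3y at 12.6, 22.7 and 34.4 CPM. These differences argue against the 7-day libraries being repeats of 1 RNA sample.

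**Figure D1:**
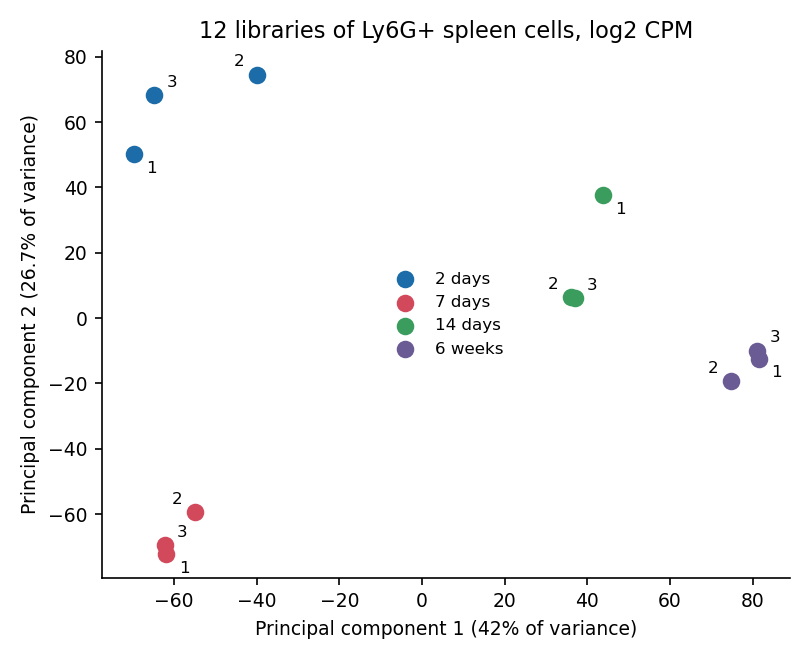
Principal components of log2 CPM for the 12 libraries, with each point a library coloured by age and labelled with its replicate number. Component 1 (42% of variance) parts the 2-day and 7-day libraries from the older ones, and component 2 (26.7%) parts 2 days from 7 days.

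Of 15494 genes tested, 10725 (69.2%) differed with age at a Benjamini-Hochberg adjusted p below 0.05. Among these genes, 3425 had their highest mean at 7 days, 2980 at 6 weeks, 2837 at 2 days and 1483 at 14 days. Against 6 weeks, 6263 genes differed at 2 days, 7905 at 7 days and 2934 at 14 days. The last of these counts moved by more than 1.5 times with single libraries: it was 4685 without 2-day replicate 2, 1709 without 6-week replicate 1 and 1677 without 6-week replicate 3. Scaling by library totals alone moved the median of all genes between 7 days and 6 weeks from -0.01 to 0.16 and that between 7 days and 2 days from -0.01 to 0.14 on the log2 scale, so changes at 7 days are relative to that shift.

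Of 29 gene lists tested with camera at a preset correlation, 13 differed at 2 days, 20 at 7 days and 12 at 14 days against 6 weeks. With the correlation between genes estimated from the libraries, camera called 0 lists in each of these comparisons, while 8, 3 and 4 lists had an unadjusted p under 0.05. The rotation test fry, which asks only whether the genes of a list move one way on balance, called 20, 21 and 12 lists. Counts of single genes are therefore given beside each list call. They are to be read against the share of all tested genes that differed from 6 weeks, in either direction: 40.4% at 2 days, 51% at 7 days and 18.9% at 14 days. Between younger ages the share was 48.7% for 7 against 2 days, 45.9% for 14 against 7 days and 25.1% for 14 against 2 days.

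**Figure D2:**
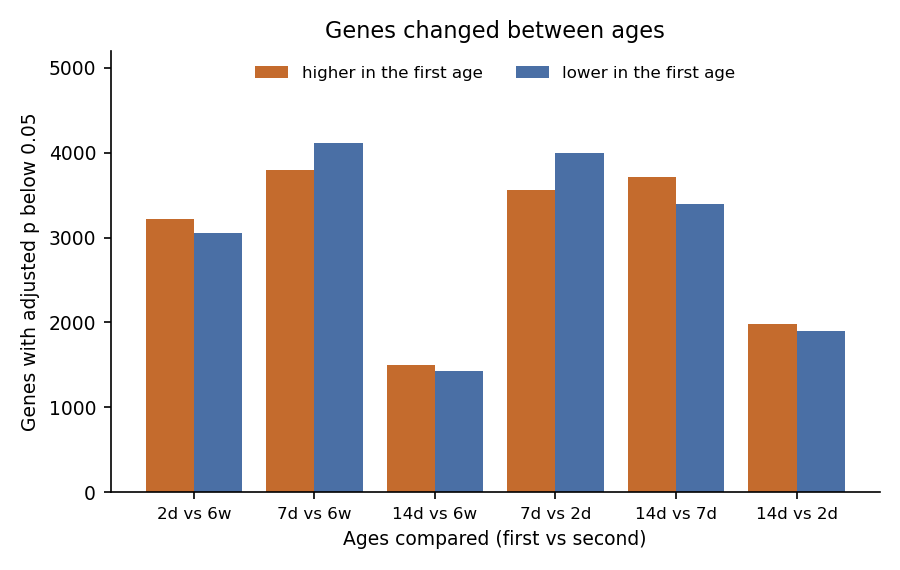
Genes with an adjusted p below 0.05 in each of the 6 comparisons between ages, as bars of genes higher and lower in the first age named. The 7-day libraries differ from 6 weeks in 7905 genes, and the 14-day libraries in 2934.

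The first comparison, of 2 days with 6 weeks, sets cells of newborn mice against those of grown mice. At 2 days 3214 genes were higher and 3049 lower, and 1602 and 1785 of them changed more than 2-fold. Genes induced by type I interferon were lower: 34 of 40 measured members fell and 0 rose, with 35 lower adjusted over the list alone and a median log2 fold change of -1.19. Camera gave the list an adjusted p of 2.51e-15 (adjusted p = 0.166 with an estimated correlation). Irf7, a transcription factor that amplifies the interferon response, stood at 125 ± 26.6 CPM against 266 ± 32.4 CPM (log2 fold change -1.09, SE 0.16, adjusted p = 0.00019). Zbp1, a sensor of viral nucleic acid, was 3.67-fold lower, and the interferon-induced GTPase gene Ifi47 was 5.99-fold lower. The receptor genes themselves did not pass the test: Ifnar1 measured 115 ± 15.3 CPM against 129 ± 11.6 CPM and Ifnar2 129 ± 14 CPM against 131 ± 9.14 CPM. Socs3, an inhibitor of cytokine signalling, was lower (log2 fold change -0.74, adjusted p = 0.0147), but not without 6-week replicate 1, where the value was -0.5. Of the 12 interferon receptor and proximal signalling genes, 0 were higher and 3 lower, or 6 lower without 2-day replicate 2, and camera did not call the list.

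Genes of class I antigen presentation fell along with the interferon-stimulated genes. Of 11 measured, 10 were lower and 0 higher, also 10 adjusted over the list alone (adjusted p = 6.9e-06 with camera, adjusted p = 0.16 with an estimated correlation). The class I heavy chain gene H2-K1 was at 331 ± 26.2 CPM against 1070 ± 72.3 CPM. Nlrc5, an activator of class I transcription, was 3.35-fold lower (SE 0.21 on the log2 scale). Markers of monocytes and macrophages, which also transcribe many interferon-stimulated and class I genes, were lower too: 14 of 17 fell and 0 rose, with 14 lower adjusted over the list alone (adjusted p = 1.88e-15, adjusted p = 0.109 with an estimated correlation). The macrophage genes Cd5l and Adgre1 were 28.2-fold and 6.18-fold lower.

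Inflammatory genes split at 2 days. Of 29 genes of the NF-kB pathway and its targets, 5 were higher and 10 lower, and 6 and 11 adjusted over the list alone. Camera did not call the list, except without 6-week replicate 2 (adjusted p = 0.0351), and its direction was down while the median log2 fold change was 0.06. Without 14-day replicate 1, 11 members were higher. Il1b, which encodes interleukin 1 beta, was at 405 ± 160 CPM against 1630 ± 397 CPM (log2 fold change -2.01, SE 0.32, adjusted p = 0.000379). Ptgs2, the cyclooxygenase of prostaglandin synthesis, measured 120 ± 28.4 CPM against 123 ± 44.2 CPM, and Nfkbia 289 ± 46 CPM against 271 ± 45.8 CPM, neither past the test. Of 20 suppressive mediators of myeloid cells, 3 were higher and 5 lower under both adjustments, with no camera call. Arg1, the arginase that consumes the arginine T cells need, was 14.6-fold higher at 2 days, at a low level of 3.21 ± 1.2 CPM, and its log2 fold change moved from 3.86 to 4.81 without 6-week replicate 2. Nos2, the inducible nitric oxide synthase, was at 4.09 ± 1.02 CPM against 1.52 ± 1.24 CPM and missed the threshold (adjusted p = 0.0554), but passed it without 2-day replicate 2, 7-day replicate 2 or 6-week replicate 1 (log2 fold changes 1.57, 1.43 and 2.31) and with DESeq2 and limma-voom (1.42 and 1.73). S100a8 and S100a9, abundant neutrophil alarmins, measured 12200 ± 3700 and 19000 ± 5350 CPM at 2 days against 12800 ± 427 and 19000 ± 546 CPM, with no call.

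Granule genes went both ways at 2 days. Of 11 primary granule genes 5 were higher and 1 lower, and 6 and 1 adjusted over the list alone. The count of 5 became 3 without 2-day replicate 3, 6-week replicate 1 or 6-week replicate 3. Mpo, the myeloperoxidase of primary granules, was at 170 ± 108 CPM against 22.6 ± 13.6 CPM (log2 fold change 2.92, SE 0.5, adjusted p = 0.000657, and 3.51 without 6-week replicate 2). Elane measured 16.1 ± 9.88 CPM against 7.17 ± 3.63 CPM without a call, which it gained without 2-day replicate 2 (1.54) or 6-week replicate 2 (1.65) and with DESeq2 (1.17). Of 14 secondary granule genes 2 were higher and 5 lower under both adjustments. Ltf, the gene of lactoferrin, was at 9010 ± 1020 CPM against 15700 ± 4090 CPM (log2 fold change -0.8, SE 0.21, adjusted p = 0.00991), and Camp, the gene of the antimicrobial cathelicidin, was 1.89-fold lower. Ngp measured 17200 ± 3310 CPM against 24100 ± 6900 CPM with no call, except without 6-week replicate 1 (log2 fold change -0.69). Camera called neither granule list. Lactoferrin and its candidate receptors gave 2 genes higher and 3 lower of 6 under both adjustments, with no camera call, and Lrp2, another candidate receptor, had 67 counts over all 12 libraries and was not tested. Mature neutrophil genes gave 4 higher and 4 lower of 18 under both adjustments, with 10 lower without 2-day replicate 2. Within that list Ly6g itself was 1.9-fold lower, and Mmp9 and Cxcr2 measured 5470 ± 1330 and 858 ± 433 CPM against 5900 ± 366 and 1390 ± 258 CPM with no call. Without 2-day replicate 2 Cxcr2 was called (log2 fold change -1.16), as with DESeq2 (-0.71) and limma-voom (-0.79). NADPH oxidase genes gave 1 lower of 7. Cell cycle genes gave 6 higher and 3 lower of 31, and 3 and 1 adjusted over the list alone. These small counts depended on single libraries: without 2-day replicate 1, 0 were higher and 10 lower, without 2-day replicate 3 and without 6-week replicate 1 only 1 was higher, and without 6-week replicate 3, 0 were. The proliferation gene Mki67 was at 166 ± 29.1 CPM against 153 ± 30.3 CPM.

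A fetal-type set was higher at 2 days. Of 12 measured members, among them imprinted growth genes and RNA-binding proteins of fetal tissue, 10 rose and 0 fell, also 10 adjusted over the list alone (adjusted p = 4.76e-11, adjusted p = 0.109 with an estimated correlation). The median log2 fold change was 5.51, or 5.35 with the 3 members that had no counts at 6 weeks set to their lower bound of 3 counts over the group. Igf2bp3, an RNA-binding protein of fetal blood formation, was at 32.9 ± 6.66 CPM against 0.928 ± 0.167 CPM (35.4-fold, log2 SE 0.19, adjusted p = 4.59e-09). Igf2bp1 was at least 47.1-fold higher, with 1.28 ± 0.0525 CPM against 0 counts. Markers of stromal and endothelial cells, some of which also transcribe imprinted genes, rose at the same age: 8 of 9 were higher and 1 lower under both adjustments (adjusted p = 0.000519, adjusted p = 0.367 with an estimated correlation), and collagen gene Col3a1 was at 16.5 ± 10.8 CPM against 0.101 ± 0.0816 CPM (log2 fold change 7.32, and 8.17 without 6-week replicate 1).

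Among genes named for the size of their change, most rises at 2 days were in genes of mast cells. Tryptase gene Tpsb2 was at 1400 ± 465 CPM against 0.0722 ± 0.0412 CPM, a level at 6 weeks that rests on 8 counts. Tpsab1 was at least 2050-fold and the mast cell receptor gene Mrgprb1 at least 1460-fold higher, both with 0 counts at 6 weeks. Cpa3, the mast cell carboxypeptidase, was 905-fold higher (693 ± 185 CPM). Eosinophil, basophil and mast cell markers gave 9 of 13 higher and 3 lower, and 9 and 4 adjusted over the list alone (adjusted p = 1.71e-05, adjusted p = 0.16 with an estimated correlation), and Ccr3, the eotaxin receptor, was among the lower ones (68.3-fold). The Y-linked Eif2s3y and Ddx3y were the other named rises, at least 1580-fold and 1260-fold. The largest falls among genes so named were in the immunoglobulin joining chain gene Jchain (451-fold), complement gene C6 (370-fold), the chemokine receptor gene Cxcr1 (171-fold, log2 SE 0.46) and Adamdec1 (80.7-fold). The log2 fold change of Jchain, -8.82, was -10.26 without 2-day replicate 1, -8.2 without 6-week replicate 1 and -9.54 with limma-voom.

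Erythroid markers rose in 15 of 21 at 2 days with 0 lower, also 15 adjusted over the list alone (adjusted p = 0.000142, adjusted p = 0.621 with an estimated correlation), among them Gata1 (38.8-fold) and Rhag (25.8-fold). Rhag's log2 fold change of 4.69 was 4.01 without 2-day replicate 1 and 5.96 without 6-week replicate 1. Of 9 megakaryocyte and platelet markers 5 were higher and 1 lower under both adjustments (adjusted p = 0.00433, adjusted p = 0.109 with an estimated correlation, and 0.066 without 2-day replicate 2). The lists of lymphoid and dendritic cells were lower. Of 14 B cell and MHC class II markers 7 fell and 0 rose, 8 adjusted over the list alone (adjusted p = 1.8e-06, adjusted p = 0.367 with an estimated correlation). Of 15 T and NK cell markers 11 fell and 2 rose, 12 and 2 adjusted over the list alone (adjusted p = 0.000743, adjusted p = 0.531 with an estimated correlation). Of 9 dendritic cell markers 7 fell and 0 rose, 7 and 1 adjusted over the list alone (adjusted p = 0.000274, adjusted p = 0.16 with an estimated correlation). Examples were Cr2 (20-fold lower, adjusted p = 1.97e-06), Cd4 (12.4-fold) and Cd209a (25.2-fold, a log2 fold change of -4.65 that was -5.36 without 2-day replicate 2).

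Of the other lists at 2 days, the unfolded protein response had 10 of 17 members lower and 2 higher, 11 and 2 adjusted over the list alone (adjusted p = 0.00618, adjusted p = 0.139 with an estimated correlation). Sdf2l1 and Creld2, which act in protein folding in the endoplasmic reticulum, were 3.85-fold and 2.31-fold lower. Pattern recognition receptors had 9 of 21 lower and 2 higher, 10 and 2 adjusted over the list alone (adjusted p = 0.0207, adjusted p = 0.696 with an estimated correlation). That call ended without 2-day replicate 1 (0.108), and 15 members were lower without 2-day replicate 2. The sensors Nod1 and Tlr9 were 3.23-fold and 3.32-fold lower. Camera called none of the remaining lists with all libraries. It called glycolysis without 2-day replicate 2 (adjusted p = 0.0274), progenitor regulators without 2-day replicate 3 (adjusted p = 0.0377) and immediate early genes without 2-day replicate 1 (adjusted p = 0.0323) or 3 (adjusted p = 0.0247). Progenitor regulators had 5 higher and 1 lower of 12, glycolysis 1 and 9 of 19, and lipid uptake and fatty acid metabolism 6 and 5 of 20. Immediate early genes had 5 and 2 of 12, and ribosomal proteins 0 and 1 of 24. Adjusted over the list alone, these counts differed only for glycolysis, with 2 higher. The 2 lower members of the immediate early list were the heat-shock genes Hspa1a and Hspa1b (log2 fold changes -2.63 and -2.5).

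**Figure D3:**
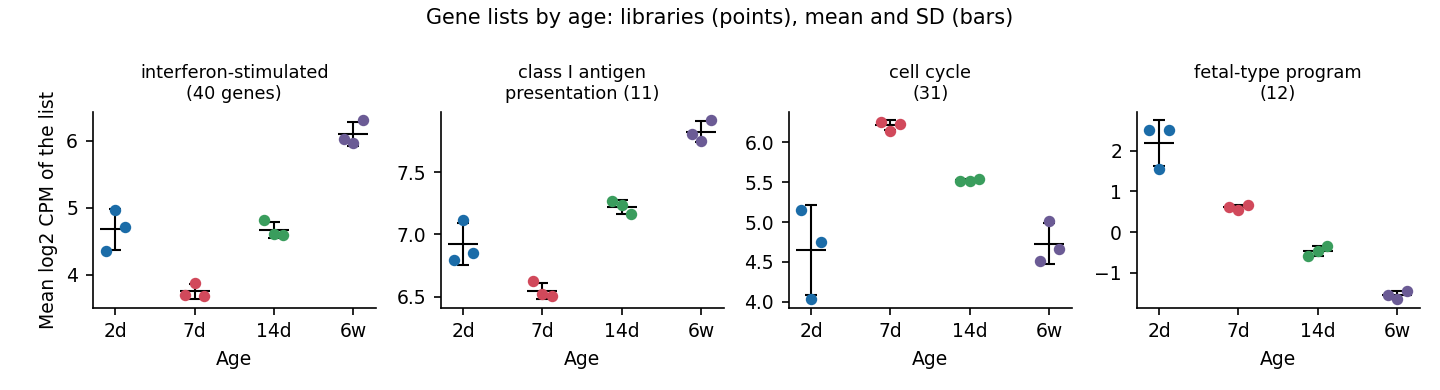
Mean log2 CPM of the members of 4 gene lists in each library, by age, with points for libraries and bars for the mean ± SD of 3 libraries. Interferon-stimulated and class I genes lie highest at 6 weeks, cell cycle genes highest at 7 days and fetal-type genes highest at 2 days.

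The second comparison, of 7 days with 6 weeks, gave the most changes against 6 weeks: 3790 genes were higher and 4115 lower, or 47.9% higher. Scaled by library totals alone, 59.3% of the called genes were higher. Heat-shock genes stood apart at this age beside all the lists below: 21 of 21 were higher than at each other age, from a list written after the data were seen, and Hspa1a was higher than at 6 weeks by 7.07 on the log2 scale. Interferon-stimulated genes were lower in 38 of 40 with 0 higher, also 38 adjusted over the list alone, with a median log2 fold change of -1.99 (adjusted p = 4.65e-31, adjusted p = 0.15 with an estimated correlation). Irf7 was at 38 ± 4.6 CPM against 266 ± 32.4 CPM (log2 fold change -2.81, SE 0.17) and Zbp1 was 10-fold lower. Unlike at 2 days, the list of interferon receptors and proximal signalling was called: 9 of 12 were lower and 1 higher under both adjustments (adjusted p = 0.00183, adjusted p = 0.419 with an estimated correlation). Its receptor chains moved apart, with Ifnar1 at 68.3 ± 6.03 CPM against 129 ± 11.6 CPM and Ifnar2 at 200 ± 4.3 CPM against 131 ± 9.14 CPM (log2 fold changes -0.92 and 0.61, SE 0.12 and 0.11). Ifngr1, a receptor chain for interferon gamma, was 2.49-fold lower, and Socs3 was at 50.9 ± 6.74 CPM against 614 ± 188 CPM. Class I antigen presentation was lower in 10 of 11 under both adjustments and higher in 0 (adjusted p = 4.96e-10, adjusted p = 0.15 with an estimated correlation), with the peptide transporter gene Tap1 4.64-fold and the proteasome gene Psmb9 3.37-fold lower.

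Inflammatory and mature neutrophil genes were lower at 7 days. NF-kB pathway genes and targets fell in 16 of 29 and rose in 2 under both adjustments (adjusted p = 0.000346, adjusted p = 0.385 with an estimated correlation). Il1b was at 76.3 ± 14.4 CPM against 1630 ± 397 CPM (log2 fold change -4.42, SE 0.35, adjusted p = 2.15e-06), and Ptgs2 at 30.6 ± 7.14 CPM against 123 ± 44.2 CPM. The subunit genes Relb and Nfkb2 were 3.38-fold and 2.53-fold lower and Nfkbia 1.71-fold. Suppressive mediators fell in 11 of 20 and rose in 2, 12 and 2 adjusted over the list alone (adjusted p = 0.00949, adjusted p = 0.44 with an estimated correlation). Cd274, which encodes the checkpoint ligand PD-L1, was 4.74-fold lower and Il4ra 3.25-fold lower. Arg1 and Nos2 measured 0.518 ± 0.11 and 1.22 ± 0.757 CPM, and S100a8 and S100a9 8980 ± 318 and 16600 ± 388 CPM, with no call for any of these. Arg1 was called without 6-week replicate 2 (log2 fold change 2.19), and S100a8 without 2-day replicate 1 or 2 (-0.48 in both) and with DESeq2 and limma-voom (-0.51 in both). Mature neutrophil genes fell in 14 of 18 and rose in 1, 15 and 1 adjusted over the list alone (adjusted p = 8.66e-05, adjusted p = 0.425 with an estimated correlation). The chemokine gene Ccl6 was 12.3-fold lower, Csf2rb 3.18-fold, Cxcr2 3.14-fold, Mmp9 1.78-fold and Ly6g 1.72-fold. Pattern recognition receptors fell in 14 of 21 and rose in 1, 18 and 1 adjusted over the list alone (adjusted p = 4.03e-07, adjusted p = 0.363 with an estimated correlation), with the adaptor gene Myd88 4.54-fold and Tlr6 8.7-fold lower. Beside these lists, 11 of 17 monocyte and macrophage markers were lower and 1 higher, 12 and 1 adjusted over the list alone (adjusted p = 0.00282, adjusted p = 0.419 with an estimated correlation). The count of 11 became 7 without 7-day replicate 3 and with library totals alone. Cx3cr1 and Ace were 4.15-fold and 4.71-fold lower.

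Genes of dividing cells were higher at 7 days. Cell cycle genes rose in 30 of 31, or 31 adjusted over the list alone, and fell in 0 (adjusted p = 1.26e-13, adjusted p = 0.363 with an estimated correlation). Mki67 was at 652 ± 33 CPM against 153 ± 30.3 CPM (log2 fold change 2.09, SE 0.16), and the mitotic motor gene Cenpe was 3.75-fold higher. Progenitor regulators rose in 7 of 12 and fell in 2 under both adjustments (adjusted p = 0.0226, adjusted p = 0.36 with an estimated correlation), among them Myb (4.54-fold) and Cd34 (14-fold). Ribosomal protein genes rose in 21 of 24 and fell in 1, 22 and 1 adjusted over the list alone (adjusted p = 0.000268, adjusted p = 0.45 with an estimated correlation), with Rps4x 1.89-fold and Rps18 2.21-fold higher. Oxidative phosphorylation genes rose in 13 of 30 and fell in 1 under both adjustments (adjusted p = 0.0261, adjusted p = 0.472 with an estimated correlation), led by Cycs (3.29-fold) and Uqcrc2 (1.44-fold). Erythroid markers, which belong to a dividing lineage, rose in 21 of 21 under both adjustments (adjusted p = 1.32e-13, adjusted p = 0.36 with an estimated correlation). The transferrin receptor gene Tfrc was at 151 ± 12.4 CPM against 19.9 ± 2.38 CPM, and haemoglobin transcripts made up 0.343% to 0.643% of the counts of 7-day libraries.

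Primary granule genes gave 4 higher and 3 lower of 11 at 7 days under both adjustments, with no camera call. Mpo was 6.25-fold and Elane 3.54-fold higher, at 141 ± 35.4 and 25.4 ± 9.08 CPM, and the log2 fold change of Mpo moved from 2.64 to 3.25 without 6-week replicate 2. Secondary granule genes gave 3 higher and 1 lower of 14, and Ltf, Camp and Ngp measured 14600 ± 1820, 4790 ± 368 and 21200 ± 1910 CPM with no call. Glycolysis genes fell in 13 of 19 and rose in 0 under both adjustments (adjusted p = 0.003, adjusted p = 0.425 with an estimated correlation), with Slc2a1 3.42-fold and Pfkp 2.2-fold lower. Cholesterol synthesis genes fell in 10 of 19 and rose in 0, 10 and 1 adjusted over the list alone (adjusted p = 0.0114, adjusted p = 0.44 with an estimated correlation), with Hmgcs1 1.73-fold lower. Camera did not call the lists of NADPH oxidase (0 higher and 2 lower of 7), the unfolded protein response (5 and 2 of 17, 5 and 1 adjusted over the list alone) or lactoferrin and its receptors (1 and 3 of 6). Lipid metabolism, with 5 higher and 8 lower of 20, was not called either. The lower count was 5 without 7-day replicate 1 or 7-day replicate 3, and the higher count 3 without 6-week replicate 1.

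Genes named for the size of their rise at 7 days were stefin A genes of chromosome 16, inhibitors of cysteine proteases, and Y-linked genes. Stfa3 was at 2040 ± 100 CPM against 2.76 ± 0.362 CPM (737-fold, log2 SE 0.33, adjusted p = 4.75e-09), BC100530 was 512-fold and BC117090 496-fold higher. Members of this cluster are close paralogs, so how reads were divided among them is uncertain. Ddx3y and Eif2s3y were at least 1320-fold and 855-fold higher. Those named for their fall were Cxcr1 (246-fold), Igfbp6 (154-fold, a log2 fold change of -7.27 that was -8.27 without 7-day replicate 2), the interferon-induced Ifit3b (73.4-fold), which shares reads with its paralogs, Fgl2 (69.3-fold, 10 ± 2.8 CPM against 696 ± 140 CPM) and Prr5l (58.2-fold). The fetal-type set had 8 of 12 higher and 0 lower under both adjustments (adjusted p = 7.81e-05, adjusted p = 0.36 with an estimated correlation), with Igf2bp3 at 23.4 ± 1.81 CPM (25.1-fold) and Igf2bp1 at least 19.6-fold higher.

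Markers of other lineages also differed at 7 days. Eosinophil, basophil and mast cell markers were higher in 9 of 13 and lower in 2 under both adjustments (adjusted p = 0.00183, adjusted p = 0.36 with an estimated correlation), with Cpa3 17.6-fold higher and Siglecf 6.94-fold lower. Stromal and endothelial markers were higher in 6 of 9 and lower in 1 under both adjustments (adjusted p = 0.00296, adjusted p = 0.385 with an estimated correlation), with Sparc 44.5-fold and Cxcl12 11.1-fold higher. Dendritic cell markers were lower in 5 of 9 and higher in 2, 6 and 2 adjusted over the list alone (adjusted p = 0.0366, adjusted p = 0.385 with an estimated correlation). That call ended without 7-day replicate 2 (0.0764), without 14-day replicate 1 (0.051) and with genes filtered at 1 CPM in 3 libraries (0.0525), and 3 members were lower with library totals alone. Itgax and Batf3 were 16.4-fold and 4-fold lower. Megakaryocyte and platelet markers were higher in 5 of 9 and lower in 0 under both adjustments (adjusted p = 0.0366, adjusted p = 0.36 with an estimated correlation), with Pf4 11.7-fold and Itga2b 2.35-fold higher. This call ended without 2-day replicate 1 (0.0638), 2-day replicate 2 (0.109), 7-day replicate 2 (0.0542) or 6-week replicate 2 (0.066), and with genes filtered at 1 CPM in 3 libraries (0.0924). Camera did not call B cell and MHC class II markers (2 higher and 5 lower of 14, 1 and 5 adjusted over the list alone), whose median log2 fold change was 0.06 with a test direction of down, or T and NK cell markers (1 and 3 of 15, median 0.26, direction down). Immediate early genes, with 3 higher and 7 lower of 12 and median -0.74, were not called. Of the 3 higher, 2 were the heat-shock genes Hspa1a and Hspa1b (log2 fold changes 7.07 and 6.46).

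**Figure D4:**
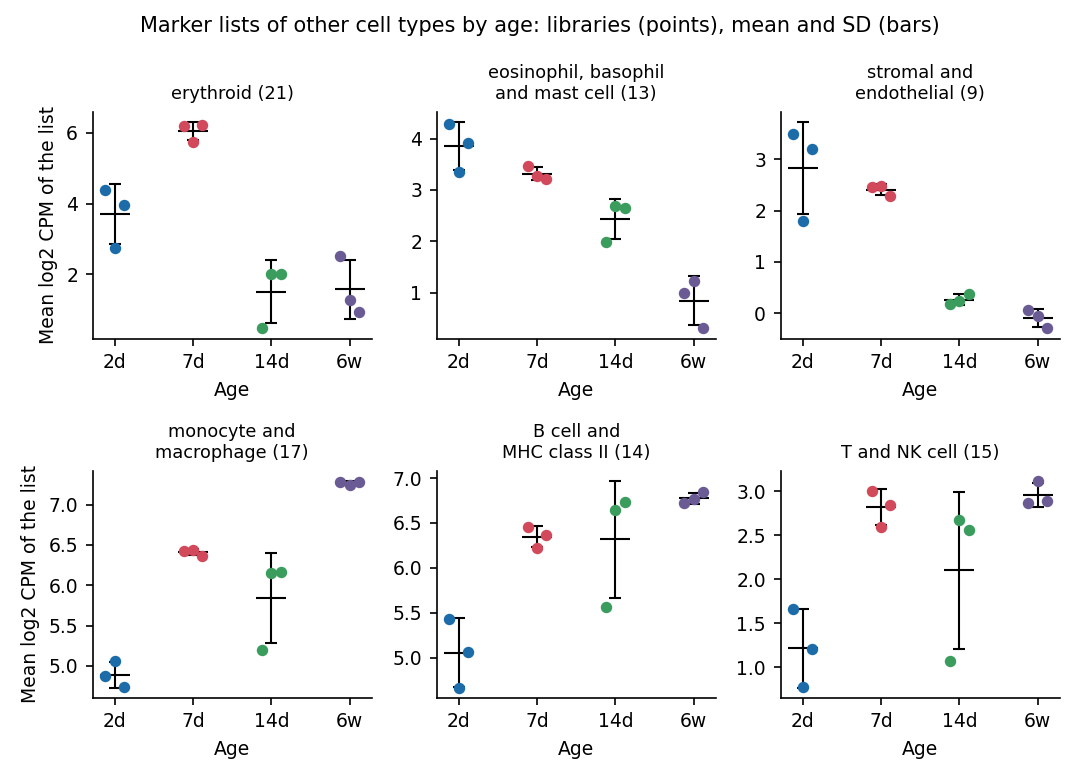
Mean log2 CPM of the markers of 6 groups of other cell types in each library, by age, with points for libraries and bars for the mean ± SD of 3 libraries. Erythroid markers lie highest at 7 days, and monocyte and macrophage markers lie lowest at 2 days.

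The third comparison, of 14 days with 6 weeks, had 1500 genes higher and 1434 lower, 2934 in all, or 51.1% higher. That count was 4685 without 2-day replicate 2, 1709 without 6-week replicate 1 and 1677 without 6-week replicate 3. Scaled by library totals alone, 58% of the called genes were higher. Interferon-stimulated genes were again lower, in 37 of 40 with 0 higher and 37 adjusted over the list alone, with a median log2 fold change of -1.33 (adjusted p = 9.35e-37, adjusted p = 0.181 with an estimated correlation). Irf7 was at 107 ± 9.3 CPM (log2 fold change -1.32, SE 0.16, adjusted p = 0.000235), and Ifi27l2a and Oas1a were 3.85-fold and 4.56-fold lower. Oas1g, of the same antiviral synthetase family and uncertain because of its paralogs, was 13.9-fold lower. Ifnar2 was at 91.7 ± 6.97 CPM against 131 ± 9.14 CPM (log2 fold change -0.51). Ifnar1 was at 97.2 ± 5.83 CPM (log2 fold change -0.41, adjusted p = 0.0339) and lost its call without 14-day replicate 2 (-0.36), 14-day replicate 3 (-0.42), 6-week replicate 1 (-0.36) or 6-week replicate 3 (-0.39). Socs3, at 349 ± 60.8 CPM, lost its call without the same 4 libraries, with values of -0.7, -0.78, -0.58 and -0.81. The list of interferon receptors and proximal signalling, with 0 higher and 4 lower of 12 under both adjustments, was not called, and 2 were lower without any of the same 4 libraries. It was called without any 1 of the 2-day libraries, 7-day replicate 3, 14-day replicate 1 or 6-week replicate 2 (adjusted p from 0.0109 to 0.049) and with relative log expression factors (adjusted p = 0.046). Class I antigen presentation was lower in 8 of 11 and higher in 0, 10 and 0 adjusted over the list alone (adjusted p = 2.02e-06, adjusted p = 0.287 with an estimated correlation), with H2-K1 2.07-fold and Tap1 1.7-fold lower. Libraries of both these ages held at most 1 Y-linked count each. Monocyte and macrophage markers were lower in 11 of 17 and higher in 2, 12 and 2 adjusted over the list alone (adjusted p = 9.21e-11, adjusted p = 0.287 with an estimated correlation), with C1qa 7.56-fold lower.

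Inflammatory genes were split at 14 days, with several higher than at 6 weeks. NF-kB pathway genes and targets rose in 12 of 29 and fell in 7, 12 and 8 adjusted over the list alone, without a camera call. Camera called the list without 14-day replicates 1, 2 and 3 in turn (adjusted p = 0.0485, 0.0138 and 0.0129). Ptgs2 was at 666 ± 246 CPM against 123 ± 44.2 CPM (log2 fold change 2.43, SE 0.32, adjusted p = 0.000348), while Il1b measured 1940 ± 684 CPM against 1630 ± 397 CPM with no call. Nfkbia was 1.61-fold higher, a call lost without 14-day replicate 1 (log2 fold change 0.42), 6-week replicate 2 (0.58) or 6-week replicate 3 (0.67). Immediate early genes rose in 4 of 12 and fell in 2, 6 and 2 adjusted over the list alone (adjusted p = 0.00683, adjusted p = 0.635 with an estimated correlation, 0.0685 with fry and 0.0732 without 6-week replicate 2). With library totals alone 7 rose. The 2 that fell in the main fit were the heat-shock genes Hspa1a and Hspa1b (log2 fold changes -2.52 and -3.01). Fosb was at 1410 ± 124 CPM against 102 ± 11.3 CPM, and Atf3 was 7.13-fold higher (log2 fold change 2.83, and 2.09 without 14-day replicate 1). These genes also respond to handling of cells. Among genes named for the size of their rise, Thbs1, the gene of thrombospondin 1, was at 3330 ± 497 CPM against 57.7 ± 11.5 CPM (57.7-fold, log2 SE 0.25, adjusted p = 1.08e-07). The AP-1 subunit gene Fosl1 was 71.9-fold higher, at 33.5 ± 33.7 CPM, and its log2 fold change moved from 6.17 to 4.92 without 14-day replicate 1. BC100530, Stfa3 and the eosinophil granule gene Prg2 were 34.1-fold, 32.6-fold and 29.1-fold higher. Those named for their fall were Cxcr1 (16.3-fold), Col14a1 (14.9-fold), Oas1g (13.9-fold), Wfdc17 (11.6-fold, 19.4 ± 19.2 CPM, a log2 fold change of -3.54 that was -4.76 without 14-day replicate 1) and Upp1 (11.1-fold). Suppressive mediators gave 4 higher and 5 lower of 20, and 5 and 7 adjusted over the list alone, with no camera call. The count of 5 lower fell to 2 without 14-day replicate 2 or 6-week replicate 1 and to 3 without 7-day replicate 2, 14-day replicate 3, 6-week replicate 2 or 6-week replicate 3. Nos2 was lower (log2 fold change -2.58, adjusted p = 0.0173), but not without 14-day replicate 2 (-2.21) or 6-week replicate 1 (-1.69). Arg1 measured 0.217 ± 0.144 CPM at 14 days, and S100a8 and S100a9 11900 ± 1540 and 17200 ± 1810 CPM, with no call.

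Cell cycle genes were higher at 14 days in 21 of 31 and lower in 0, 27 and 0 adjusted over the list alone (adjusted p = 3.35e-11, adjusted p = 0.513 with an estimated correlation). The count was 13 with library totals alone, 10 without 14-day replicate 1 or 14-day replicate 2, 11 without 14-day replicate 3, and 7 without 6-week replicate 1 or 6-week replicate 3. Mki67 was at 328 ± 11.5 CPM against 153 ± 30.3 CPM (log2 fold change 1.1, SE 0.16), and Cenpe was 2.27-fold higher. Secondary granule genes rose in 5 of 14 and fell in 0 under both adjustments (adjusted p = 0.00384, adjusted p = 0.487 with an estimated correlation), with Olfm4 3.95-fold and Chil3 1.77-fold higher. Ltf, Camp and Ngp measured 15100 ± 1820, 5650 ± 296 and 28800 ± 1740 CPM with no call, apart from Camp without 2-day replicate 2 (log2 fold change 0.41) and with DESeq2 (0.38). Primary granule genes gave 0 higher and 1 lower of 11, with Mpo and Elane at 33.2 ± 7.15 and 10.6 ± 3.43 CPM and no call. Cxcr2 was 2.27-fold lower, a call lost without 14-day replicate 2 (log2 fold change -1.1), 6-week replicate 1 (-1.06) or 6-week replicate 3 (-1.16). Mmp9 and Ly6g measured 4000 ± 828 and 168 ± 18.4 CPM with no call, apart from Mmp9 without 2-day replicate 1 (-0.56), 2-day replicate 2 (-0.55) or 14-day replicate 1 (-0.74) and with DESeq2 (-0.58). The fetal-type set was higher in 4 of 12 and lower in 0, 5 and 0 adjusted over the list alone (adjusted p = 0.000188, adjusted p = 0.297 with an estimated correlation). Its median log2 fold change was 1.68, or 1.07 with 3 members at their bound. Igf2bp3 was still at 22.8 ± 1.03 CPM, 24.5-fold above 6 weeks, and Mest was 3.15-fold higher.

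Lactoferrin and its candidate receptors had 3 of 6 lower and 0 higher at 14 days under both adjustments (adjusted p = 0.0399, adjusted p = 0.287 with an estimated correlation). Itln1, an intestinal lectin named as a lactoferrin receptor, was at least 131-fold lower, with 0 counts against 3.63 ± 0.993 CPM. Lrp1 was 1.49-fold lower, but not without 6-week replicate 2 (log2 fold change -0.52) or 6-week replicate 3 (-0.56), and without the latter only 1 member was lower. The list's call was fragile. Its adjusted p rose to 0.106 without 2-day replicate 2, and to 0.0785, 0.084 and 0.0737 without 7-day replicates 1, 2 and 3. It rose to 0.122, 0.147 and 0.146 without 14-day replicates 1, 2 and 3, and to 0.109, 0.0731 and 0.119 without 6-week replicates 1, 2 and 3.

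Further lists were called at 14 days. Cholesterol synthesis genes fell in 7 of 19 and rose in 0, 10 and 0 adjusted over the list alone (adjusted p = 0.00899, adjusted p = 0.635 with an estimated correlation, and 0.0731 without 6-week replicate 2). The count was 2 without 14-day replicate 1, 6-week replicate 2 or 6-week replicate 3, and 1 with library totals alone. Cyp51 and Stard4 were 2.09-fold and 1.68-fold lower. Pattern recognition receptors fell in 6 of 21 and rose in 0 under both adjustments (adjusted p = 0.0102, adjusted p = 0.682 with an estimated correlation, and 0.109 with fry), with Casp4 2.75-fold and Myd88 1.88-fold lower. Eosinophil, basophil and mast cell markers rose in 4 of 13 and fell in 1 under both adjustments (adjusted p = 0.00384, adjusted p = 0.372 with an estimated correlation). Ear1, an eosinophil ribonuclease gene with close paralogs, was 120-fold higher (log2 fold change 6.91, and 7.73 without 6-week replicate 2). T and NK cell markers fell in 4 of 15 and rose in 0, 5 and 0 adjusted over the list alone (adjusted p = 0.00683, adjusted p = 0.635 with an estimated correlation, 0.0761 with fry and 0.143 without 14-day replicate 1), with Klrb1c 2.89-fold and Nkg7 2.7-fold lower. Camera called none of the rest with all libraries. Erythroid markers gave 3 higher and 1 lower of 21 under both adjustments, with 1 higher without 14-day replicate 2, 6-week replicate 2 or 6-week replicate 3. B cell and MHC class II markers gave 0 higher and 1 lower of 14, or 0 lower adjusted over the list alone, and were called without 14-day replicate 2 (adjusted p = 0.0164) or 14-day replicate 3 (adjusted p = 0.00462). Megakaryocyte and platelet markers gave 2 and 0 of 9, or 3 higher adjusted over the list alone, and dendritic cell markers 0 and 0 of 9. Glycolysis gave 0 higher and 3 lower of 19 and was called without 2-day replicate 2 (adjusted p = 0.0463), 14-day replicate 1 (adjusted p = 0.00911) or 6-week replicate 3 (adjusted p = 0.0376). The unfolded protein response gave 3 and 6 of 17 and was called without 2-day replicate 1 (adjusted p = 0.0483), 2-day replicate 2 (adjusted p = 0.0311) or 6-week replicate 1 (adjusted p = 0.044). Mature neutrophil genes gave 2 and 4 of 18 and were called without 2-day replicate 2 (adjusted p = 0.0365) or 14-day replicate 1 (adjusted p = 0.0493). Progenitor regulators gave 2 and 0 of 12 and were called without 14-day replicate 1 (adjusted p = 0.04). Without single libraries the lower count of glycolysis lay between 0 and 7 and that of mature neutrophil genes between 0 and 9.

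**Figure D5:**
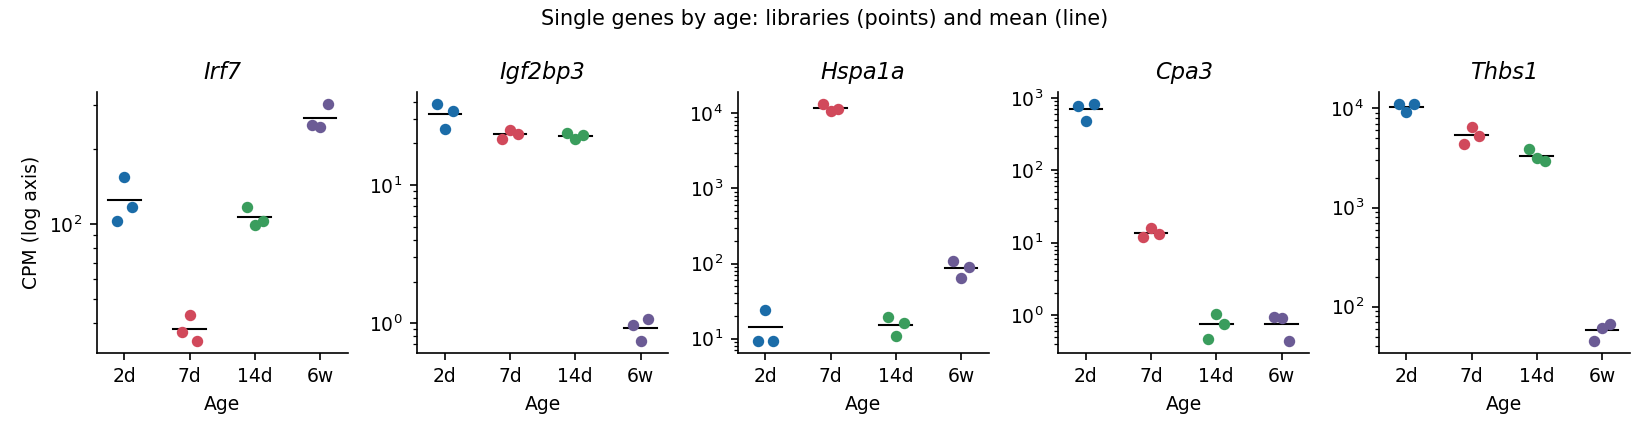
CPM of 5 genes in each library by age, on a log axis, with points for libraries and a line at the mean of 3. Igf2bp3 stays at 22.8 CPM or more on average up to 14 days against 0.928 CPM at 6 weeks, and Hspa1a stands out at 7 days, at 11800 CPM.

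The last comparisons, between the 3 younger ages, ask how the cells moved from one age to the next. From 2 to 7 days, 3555 genes rose and 3991 fell, 7546 in all, or 47.1% higher. Scaled by library totals alone, 57% of the called genes were higher. Hspa1a, Hspa1b and Hspa1l, chaperone genes of the heat-shock response that lie side by side on chromosome 17, had the largest rises by the naming rule. Hspa1a was at 11800 ± 1390 CPM at 7 days against 14.4 ± 8.61 CPM at 2 days (log2 fold change 9.69, SE 0.5, adjusted p = 2.12e-07), and Hspa1b at 8760 ± 961 CPM against 17.7 ± 13.1 CPM (log2 fold change 8.96). Without 2-day replicate 2 these values were 10.32 and 9.78. Hspa1a and Hspa1b are near-identical copies, so the split of reads between them is uncertain. Hspa1a and Hspa1b took 1.93% to 2.55% of all counts in 7-day libraries. The falls named by that rule were in genes found in mast cells: Tpsab1 145-fold, Tpsb2 71.5-fold and the serotonin transporter gene Slc6a4 60.1-fold. Cell cycle genes rose in 30 of 31, erythroid markers in 20 of 21 and monocyte and macrophage markers in 13 of 17, whereas interferon-stimulated genes fell in 25 of 40 and rose in 2. These list counts between 2 and 7 days and between 7 and 14 days have no list test.

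From 7 to 14 days, 3713 genes rose and 3395 fell, 7108 in all, or 52.2% higher. Scaled by library totals alone, 46.2% of the called genes were higher. Hspa1a fell to 15.4 ± 4.18 CPM (767-fold), and Ddx3y and Eif2s3y fell at least 1290-fold and 838-fold. Il1b rose from 76.3 ± 14.4 to 1940 ± 684 CPM (log2 fold change 4.67, SE 0.36, adjusted p = 2.85e-06), Fgl2 rose 42.7-fold and Cass4, an adhesion scaffold gene, 69.1-fold (log2 fold change 6.11, and 5.51 without 14-day replicate 1). Interferon-stimulated genes rose in 27 of 40 and fell in 1, NF-kB genes rose in 19 of 29 and fell in 2, and erythroid markers fell in 21 of 21.

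Between 2 and 14 days 3882 genes differed, 1978 higher and 1904 lower at 14 days, and the count was 5833 without 2-day replicate 2. Fitted on the libraries of these 2 ages alone, it was 1952. NF-kB genes were higher at 14 days in 15 of 29 and lower in 5, 17 and 5 adjusted over the list alone (adjusted p = 0.000505, adjusted p = 0.531 with an estimated correlation), with 3 lower without 2-day replicate 3. Cell cycle genes were higher in 22 of 31 under both adjustments (adjusted p = 1.31e-08, adjusted p = 0.531 with an estimated correlation). The fetal-type set was lower in 9 of 12, 10 adjusted over the list alone (adjusted p = 2.12e-08, adjusted p = 0.169 with an estimated correlation). Interferon-stimulated genes gave 9 higher and 6 lower of 40, and 9 and 8 adjusted over the list alone, with no camera call. Single libraries moved these small counts: 5 were higher without 14-day replicate 2, 14 lower without 2-day replicate 1, and 3 lower without 2-day replicate 3 or 14-day replicate 3. Camera called 10 of the 29 lists here, and the other 7 were markers of other cell types. Erythroid markers were lower in 13 of 21, 19 adjusted over the list alone (adjusted p = 0.531 with an estimated correlation), and stromal and endothelial markers in 8 of 9 (adjusted p = 0.404 with an estimated correlation). For the next 5 lists the adjusted p with an estimated correlation stands first in parentheses. Monocyte and macrophage markers were higher in 8 of 17 (adjusted p = 0.404), and in 13 without 14-day replicate 1. B cell and MHC class II markers were higher in 6 of 14, 7 adjusted over the list alone (adjusted p = 0.531), and dendritic cell markers in 7 of 9 (adjusted p = 0.169). Megakaryocyte and platelet markers were lower in 6 of 9 (adjusted p = 0.169), in 3 without 14-day replicate 3, and lost their camera call without 2-day replicate 2 (adjusted p = 0.0822). Eosinophil, basophil and mast cell markers were higher in 4 of 13 and lower in 6, 5 and 6 adjusted over the list alone (adjusted p = 0.418), with a direction of down although the median log2 fold change was 0.62, and lost their camera call without 14-day replicate 1 (adjusted p = 0.238). Some lists gained a camera call with 1 library left out. T and NK cell markers did so without 14-day replicate 1 (adjusted p = 2.09e-06) or 2-day replicate 1 (adjusted p = 0.0493). Primary granule genes, class I genes (adjusted p = 0.0257 for both), pattern recognition receptors (adjusted p = 0.0452) and the unfolded protein response (adjusted p = 0.0422) did so without 2-day replicate 2. The unfolded protein response also did without 14-day replicate 2 (adjusted p = 0.031), and secondary granule genes without 6-week replicate 1 (adjusted p = 0.0408). Ace, a monocyte-lineage enzyme gene, rose 21.3-fold (13.5 ± 5.09 to 288 ± 29.3 CPM), Adamdec1 50.8-fold and Ccr3 17-fold, and Tpsab1 and Mrgprb1 fell at least 2010-fold and 1430-fold.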

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

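Of the tests in this part, those of the heat-shock genes were chosen after the result was seen. Groups of 3 libraries are too small for a test of single libraries far from the rest, so none was made.

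Some named genes stood above the 6-week level at one age and below it at another, with the difference between those ages past the edgeR test. Ace moved by 3.03 on the log2 scale from 7 to 14 days and by 4.42 from 2 to 14 days. Ifnar2 moved by -1.13 from 7 to 14 days, from above the 6-week level to below it. Nfkbia rose by 1.47 and Ptgs2 by 4.44 over the same step. Chil3, a secondary granule gene, rose by 2 between 2 and 14 days. Y-linked transcripts, which no comparison was about, summed to 90.5 ± 15.8 CPM at 2 days and 70.7 ± 28.4 CPM at 7 days, against at most 1 count per library at the older ages.

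The heat-shock genes Hspa1a and Hspa1b differed in the same way, by 9.69 and 8.96 from 2 to 7 days (10.32 and 9.78 without 2-day replicate 2) and by -9.58 and -9.47 from 7 to 14 days. Of a list of heat-shock genes written after this was seen, 21 of 21 measured were higher at 7 days than at each other age. RNA from another cell type cannot be told apart from a change in neutrophils. Erythroid markers had the largest median rise from 2 to 7 days of the 8 marker lists. They would predict 2600 CPM of Hspa1a at 2 days, where 14.4 CPM were found, but only if those cells held as much Hspa1a at both ages. Other cells stressed at 7 days alone stay open. Sorting for Ly6G is meant to remove erythroid and other cells, but haemoglobin transcripts made up 0.343% to 0.643% of the counts of 7-day libraries. A difference in how the 7-day cells were handled or processed may explain the pattern and cannot be told apart from age, since the labels give no batch and every 7-day library shows it, and this holds for the other changes at 7 days as well. A response of the cells at that age stays open as well and was not tested.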

How the results depend on the processing

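No named gene or list call changed sign under the alternatives examined for it. Calls were not compared 1 by 1 with upper-quartile factors, library totals alone, no filter, erythroid genes left out or fits on only 2 ages. DESeq2 and limma-voom were compared for genes only. The count of genes changed between 2 days and 6 weeks lay between 4731 and 8170 with 1 library left out, and that between 7 days and 6 weeks between 6586 and 9326. For 14 days against 6 weeks the range was 1677 to 4685, and without both libraries that stood apart, an alternative chosen after the data were seen, the count was 4869. For 14 days against 2 days the range was 2678 to 5833, with 6249 without both of these libraries and 1952 with only the 2 ages in the fit. The other counts ranged from 6077 to 8129 for 7 days against 2 days, 5564 to 8728 for 14 against 7 days and 9478 to 12373 for any age. All other alternatives stayed within 1.5 times the main counts, and the causes of the larger moves were not tested. Lists called ranged from 13 to 15, 18 to 20 and 10 to 15 against 6 weeks, and 10 to 13 for 14 days against 2 days. With an estimated correlation 0 were called in each of these 4 comparisons, where 8, 3, 4 and 3 lists had an unadjusted p under 0.05. Fry called 20, 21, 12 and 15. With 1 library left out camera ended 23 calls and gained 33 among 1392 list results examined, called or not in the main fit. Of 196 named gene results, called or not, DESeq2 gained 6 calls and lost 0, and limma-voom gained 3. With 1 library left out 20 gene calls ended and 14 were gained among 2352 results examined. Without both libraries that stood apart, 10 list calls and 7 gene calls were gained and 5 and 0 ended. Without all 7-day libraries 2 gene calls ended, at 14 days Ifnar1 (-0.41) and Nfkbia (0.69), and 0 list calls changed. Both fits were chosen after the data were seen. Replicate numbers did not pair the libraries: 2 of 18 same-numbered pairs correlated over 0.1 and 1 of 12 libraries correlated best with its own number. With the replicate number as a block the counts were 5672, 7459 and 2346 against 6 weeks and 10020 for any age, and the block ended 1 list call (lactoferrin and its receptors at 14 days, 0.0549) and 1 gene call (Ifnar1 at 14 days). At these depths counting error limits only genes near 0 counts.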

Other observations

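Genes named in this part were chosen after their values were seen, and the tests of the interferon-stimulated genes and of transcripts found only at 6 weeks were chosen after the result was seen. Those of the let-7 targets and of other splits of the libraries were set beforehand.

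The stefin A genes of chromosome 16, between positions 36156811 and 36455392 (GRCm38), were far higher in the first week than later. Stfa1 was at 7508 ± 2240 CPM at 2 days, 4432 ± 375 CPM at 7 days, 246.8 ± 36.5 CPM at 14 days and 18.6 ± 2.65 CPM at 6 weeks, with each younger age above 6 weeks by the edgeR test (log2 fold changes 8.66, 7.9 and 3.73). Stfa2, at 3827 ± 1290, 1870 ± 102, 131 ± 25.9 and 6.07 ± 1.35 CPM, and Stfa3 followed the same order. Stfa2l1 fell less far, to 127 ± 41.1 CPM. How reads were divided among these paralogs is uncertain. Mast cell protease genes on chromosome 14 fell earlier. Mcpt4 went from 1025 ± 365 CPM at 2 days to 21.2 ± 4.19 CPM at 7 days (log2 fold change -5.59, SE 0.35) and 0.109 ± 0.00279 CPM at 6 weeks, and Cma1 from 842 ± 255 to 14.8 ± 2.52 CPM (log2 fold change -5.83). H19, an imprinted RNA of fetal tissues, was at 11.4 ± 5 CPM at 2 days and 1.11 ± 0.485 CPM at 7 days (log2 fold change -3.35, SE 0.54).

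Constant-region genes of switched antibodies, transcribed by plasma cells, appeared late. Igha was at 0.53 ± 0.472 CPM at 2 days, 0.869 ± 0.401 CPM at 7 days, 10.7 ± 12.5 CPM at 14 days and 539 ± 303 CPM at 6 weeks. The 14-day libraries held 25, 2.04 and 5.02 CPM and the 6-week libraries 880, 436 and 301 CPM. Ighg2b stayed at or below 0.618 ± 0.0498 CPM up to 14 days and was at 43.3 ± 19.7 CPM at 6 weeks. Ighm, which naive B cells transcribe, differed far less, with 361 ± 80.2 CPM at 2 days and 733 ± 66 CPM at 6 weeks. Sorting for Ly6G is meant to remove B and plasma cells, so these levels may be of such cells or of their RNA carried through the sort, which was not tested. Some transcripts were near absent outside 1 age, with at least 1 CPM in each of its libraries and at most 9 counts in the other 9 libraries together. There were 5 at 2 days, 2 at 7 days, 0 at 14 days and 6 at 6 weeks. Calca, the gene of calcitonin and its related peptide, was found at 2 days (12.5 ± 6.64 CPM), as were Smpx, Dclk3, Hapln1 and the chymase gene Cma2. At 7 days they were Rmrp and an unnamed gene. Pcolce2 was the 1 gene that met the reverse rule, with 0.0286 ± 0.00384 CPM at 2 days against 13.3 ± 0.293 CPM at 6 weeks.

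Genes induced by type I interferon were lower at each younger age than at 6 weeks by camera at its preset correlation, though not with an estimated correlation (adjusted p = 0.166 at 2 days, 0.15 at 7 days and 0.181 at 14 days). The 2 lists moved apart from 2 to 7 days, so a changed amount of macrophage RNA alone does not account for that step. This holds only if those cells held as much interferon-stimulated RNA at both ages, which was not tested. The median log2 fold change of the interferon list was -0.868, with 25 of 40 members lower, and that of the macrophage markers 1.687, with 13 of 17 higher. Against 6 weeks, however, both lists were lower at 2, 7 and 14 days. Medians were -1.19, -1.99 and -1.33 for the interferon list and -2.63, -1.02 and -1.47 for the macrophage markers. More macrophage RNA at 6 weeks therefore stays open as a cause of the step to that age. Sex is argued against at 14 days, where 37 members of the interferon list were lower than at 6 weeks although both ages lacked Y-linked transcripts. It cannot be told apart from age at 2 and 7 days, where every library held at least 1816 Y-linked counts. A strain difference between the 6-week mice and the younger ones could add to the step to 6 weeks and cannot be told apart from age, since the labels give no strain, although 28 members also differed between 14 and 7 days. A change of the cells or of their exposure to interferon with age stays open and was not tested.

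The 6 transcripts found only at 6 weeks were Gm26825 (199 ± 64.1 CPM), Ifi202b (15 ± 1.7 CPM), Itln1 (3.63 ± 0.993 CPM), Gm9008, Crocc2 and Jhy. RNA of another cell type cannot be told apart from the alternatives: had Gm26825 fallen no more than Igha, 427 counts would be predicted at 14 days (141 with 14-day replicate 1 left out of the Igha level), and 0 were found, but that assumes cells of an unchanged profile whose share fell no more than Igha. For the other 5 transcripts, with 52.2 counts predicted (17.2 with 14-day replicate 1 left out) and 8 found, the counts are too few as well. A test of a strain difference did not decide: Itln1 and Ifi202b start 2.44 Mb apart on chromosome 1, and a share of 0.049 of 10000 random draws of as many genes held a pair as close, but that test was made because the pair had been seen, and the share lies too near 0.05 to decide. Strain, for which the labels give nothing, may thus explain part of the pattern and cannot be told apart from age, which stays open and was not tested.

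A hypothesis set beforehand was that Lin28b, which blocks the microRNA let-7 in fetal blood cells, may leave let-7 targets higher in young cells. Lin28b was at 2.21 ± 0.834 CPM at 2 days, 0.916 ± 0.289 CPM at 7 days and 0.0451 ± 0.0413 CPM at 14 days, with 0 counts at 6 weeks. Of 16 let-7 targets measured outside the fetal-type list, 9 were higher and 4 lower at 2 days, with a median log2 fold change of 0.48. Camera gave p = 0.074 for that list (p = 0.0917 with an estimated correlation), 0.334 at 7 days and 0.36 at 14 days. The bound written beforehand took a p of 0.05 or more as evidence against the hypothesis, which was wrong, because a missed threshold does not show that the targets did not differ. The hypothesis is neither supported nor excluded.

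For pairs of ages, 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 6263 genes for 2 days, 7905 for 7 days and 2934 for 14 days against 6 weeks, where the highest of the other splits gave 0, 0 and 1. For 7 against 2 days, 14 against 7 days and 14 against 2 days the real split gave 7546, 7108 and 3882 genes and the highest other 0, 0 and 1. In each of these 6 comparisons the real split was the 1 with as many genes. Gene lists called by camera at its preset correlation numbered 13, 20 and 12 against 6 weeks and 10 for 14 against 2 days, where the highest other splits gave 17, 17, 16 and 18. As many lists as in the real split came from 5, 1, 4 and 5 of the 10 splits. Of 100 splits of the 12 libraries into 4 groups of 3, the real one included, 1 gave as many genes changed with any age. The real count was 10725 and the highest other 2996. This argues against a chance split of these libraries only. Chance differences between mice or preparations are not excluded, since no label says whether the 3 libraries of an age came from separate mice.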
